A study of Mus musculus with 160 samples.

How the data were processed

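RNA from the lungs of 160 male mice, 8 for each of 20 combinations of dose (vehicle, 10, 20, 40 or 80 µg of multiwalled carbon nanotubes) and day (1, 7, 28 or 56), was measured on Agilent arrays with 2 colours. Per the labels' protocols, mice were housed singly, total RNA was extracted with a column kit, and lung RNA was labelled with Cy3 and a commercial mouse reference RNA with Cy5 on every array, with no dye swap. Replicate numbers came from the labels. Mice of one group were taken as separate animals, so the p-values measure the spread between mice and their arrays together. No array files from the scanner were used here.

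The values analysed were the log ratios deposited in the series table, read as log2 values. Per the submitters' processing notes, Agilent Feature Extraction version 10 was used, and the filter, the normalization and the log base are not given in the sources used here. The base was read from the values. They ran from -12.47 to 11.65, too wide for a logarithm to base 10, so the base was taken as 2, with the natural logarithm not excluded. Base changes the folds and the counts of features past 1.5-fold but no p-value. The array medians ran from -0.559 to -0.031, so arrays had not been centred exactly on 0. No pair of arrays correlated below 0 (lowest r = 0.445, highest 0.980), so all arrays were taken to run in one direction, and no pair held identical values. Which channel is the numerator was not stated. The check planned for this, by the sign of genes specific to lung or to dividing cells, needed gene names and was not run.

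The table gave feature numbers as the only identity of a row, and no table used here paired them with genes. Gene lists fixed in advance (camera tests), the choice of one probe per gene and the naming of genes were therefore not run, and counts are of features. A gene can have several features. By a rule fixed before the data were examined, named items had the largest rise or fall among calls at 80 µg that lay on one side of the vehicle median in at least 7 of 8 arrays. As features without gene names, only the 2 with the largest rise and the 2 with the largest fall at day 1 are given and followed across days.

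Of 45018 features, 43378 had a value on at least 1 array and 19216 on every array. Missing values were left missing. A feature was tested in a comparison when each group in it had at least 3 values, a rule set after the file was seen and before any test. The main model was a group-means fit over all 160 arrays with limma (version 3.58.1) in R (version 4.3.3), with empirical Bayes moderation of the variance and Benjamini-Hochberg adjustment within each comparison at 0.05. Tables were read with data.table (version 1.17.8). The number of calls that changed by at least 1.5-fold was given beside the count. Comparisons were each dose against vehicle of the same day, a linear trend over dose within each day, the difference of the 80 µg change between each later day and day 1, and an F test over days in vehicle lungs. The 20-group fit shares one estimate of the spread.

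The model was tested on simulated data with the missing values, means and spreads of the real arrays, for 80 µg against vehicle at day 1 over 39714 features. Of 200 features changed by known amounts, 48% were found at 1.5-fold and 72% at 2-fold, and 5 of 125 calls were false. The simulation drew arrays independently, so it did not include the array structure seen in the real data. The number of arrays limits the precision, and depth has no counterpart here.

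Alternatives set before the data were examined were centring each array on its median, quantile normalization, fitting only the arrays of the day or groups compared, the replicate number as a block within day, array quality weights, a robust variance estimate, restriction to features in the upper 50% by interquartile range, and the rank of the dose in trends. Chosen after seeing the data were scaling each array to a common spread, leaving out the 16 arrays with a standard deviation under 1, leaving out the 10 arrays over 3 scaled median absolute deviations from their day's median on component 1, and using only features with a value on every array. For each comparison, 100 splits of its arrays into groups of the same sizes were drawn. Overlaps between days were set against the number of shared features that independent lists would give. Figures were drawn with Matplotlib (version 3.10.9) in Python (version 3.11.15).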

Results

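Gene expression was measured in whole lung from male C57BL/6J mice, a common inbred strain, after a single pharyngeal aspiration of multiwalled carbon nanotubes. In this procedure a droplet placed at the back of the throat is breathed in, which delivers the particles to the airways and alveoli. Mice received vehicle or nanotubes at 10, 20, 40 or 80 µg and were killed 1, 7, 28 or 56 days later. The 20 groups of dose and day held 8 mice each, for 160 arrays. On every array the lung RNA, labelled with Cy3, was set against a commercial reference RNA labelled with Cy5. The comparisons asked how the lung transcript profile depended on dose at each day, how it depended on time at 80 µg, and how it varied across days without nanotubes.

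The table held log ratios for 45018 array features, a feature being a single spot. Features carried only a number and were not paired with genes, so all results refer to features and none to named genes. A higher or lower ratio below means the deposited value itself. Which channel is its numerator was not stated, so a higher ratio is not read as higher expression in lung. Folds assume that the logarithm is to base 2, which the sources used here did not state.

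The arrays differed widely in quality. The standard deviation of an array's ratios ran from 0.448 to 1.86 with a median of 1.54, and 16 arrays lay under 1. Arrays of low spread had the most features with a value: between 29236 and 43347 features had a value per array, with a median of 37752.5. In a principal component analysis, component 1 held 36.8% of the variance and separated most day 28 arrays from those of the other days. On that component 10 arrays lay over 3 scaled median absolute deviations from the median of their day, of which 7 were day 28 arrays and 3 were day 7 arrays. The labels named no slide or hybridisation batch.

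**Figure D1:**
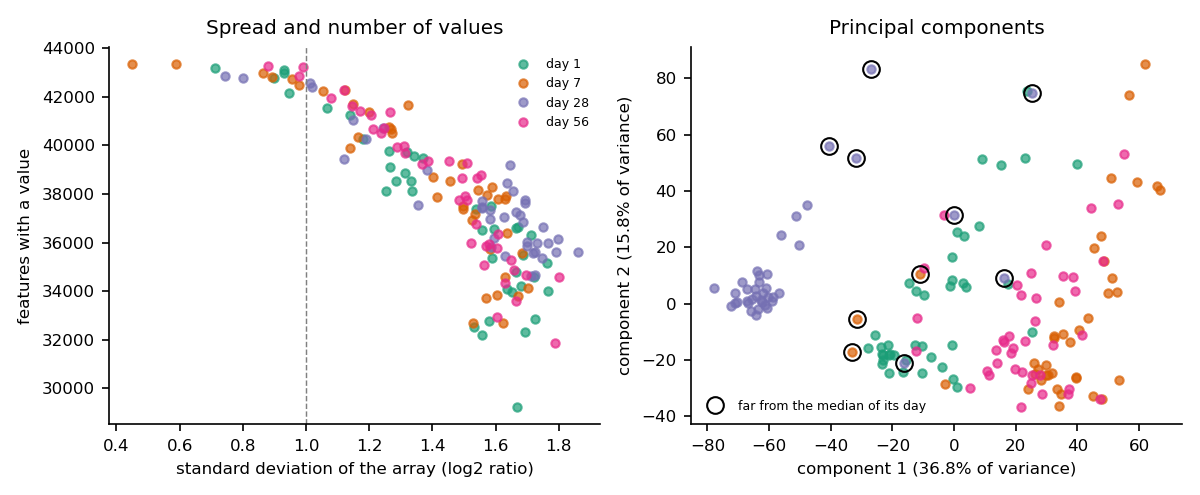
Each point is one of the 160 arrays, coloured by day. The left panel plots the number of features with a value against the standard deviation of the array's log2 ratios, with a dashed line at 1, and the right panel plots the first 2 principal components, with the 10 arrays far from the median of their day circled. Arrays of low spread had the most values, and most day 28 arrays formed a separate cloud.

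One day after aspiration, the number of changed features was larger at each higher dose in the main fit. With array quality weights the order of 40 and 80 µg was reversed (12404 and 10168 features). At 80 µg, 5708 of 39714 tested features differed from vehicle, 2997 with a higher and 2711 with a lower ratio, and 1875 of them differed by at least 1.5-fold. At 40 µg 4058 features were changed (2479 higher, 1579 lower), at 20 µg 2358 (1538 higher, 820 lower) and at 10 µg 805 (70.6% higher, 237 lower). The median change of the called features at 80 µg was 0.47 for the higher and -0.44 for the lower ones on the log2 scale, against a median standard error of 0.19. Feature 36981 had the largest rise at 80 µg, from -3.98 ± 1.26 (SD, n = 8) in vehicle lungs to -1.27 ± 1.29 at 10 µg (n = 8), -0.04 ± 0.49 at 20 µg (n = 8), 0.97 ± 0.43 at 40 µg (n = 8) and 1.36 ± 0.26 at 80 µg (n = 7). The change at 80 µg was 5.34 ± 0.47 (SE), a 40.6-fold higher ratio (limma adjusted p = 6.46e-19), with all 7 measured arrays above the vehicle median. Feature 26374 rose by 5.30 ± 0.42 (SE; limma adjusted p = 7.42e-22), above the vehicle median in 8 of 8 arrays. Its group means, such as -4.00 ± 1.04 (n = 8) in vehicle lungs and 1.30 ± 0.31 at 80 µg (n = 8), lay so close to those of feature 36981 that the pair is not counted as independent evidence. Feature 34474 fell by 2.44 on the log2 scale at 80 µg, from 5.90 ± 0.48 (SD, n = 8) to 3.45 ± 0.91 (n = 7; limma adjusted p = 1.90e-06), and was at 3.36 ± 0.66 at 40 µg (n = 8). Feature 19066 fell by 2.34, from 4.37 ± 1.44 (n = 8) to 2.03 ± 1.48 (n = 7; limma adjusted p = 0.0168).

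Quantile normalization gives every array one distribution of values. At day 1 it gave 3602 features at 80 µg, 2435 at 40 µg, 657 at 20 µg and 184 at 10 µg. Of these, 2968, 1685, 603 and 170 were also called as deposited. Under this normalization the share of higher ratios among the calls rose from 65.2% to 81.4% at 20 µg. It rose from 70.6% to 93.5% at 10 µg, and fell from 61.1% to 51.9% at 40 µg.

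**Figure D2:**
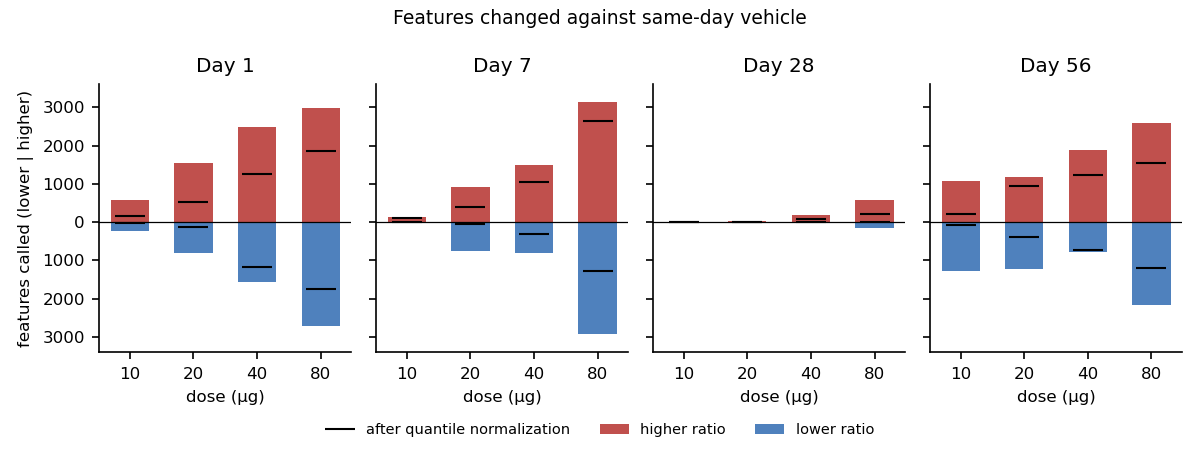
Bars give the number of features with a higher (red, upward) or lower (blue, downward) ratio than same-day vehicle at an adjusted p under 0.05, by dose in µg and by day, with 8 arrays per group. Black marks give the same counts after quantile normalization; at 80 µg the totals were 5708, 6069, 724 and 4784 at days 1, 7, 28 and 56 as deposited, and 3602, 3917, 217 and 2755 after it.

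At day 7 the counts again were larger at higher doses in the main fit. Without the arrays of low spread 40 µg gave slightly more than 80 µg (4255 and 4170 features). At 80 µg 6069 of 40090 tested features were changed, 3141 with a higher and 2928 with a lower ratio, and 1980 by at least 1.5-fold. The lower doses gave 2296 features at 40 µg (1490 higher, 806 lower), 1686 at 20 µg (920 higher, 766 lower) and 131 at 10 µg (127 higher, 4 lower). Feature 36981 was higher than vehicle by 2.92 ± 0.47 (SE) at 80 µg, a 7.59-fold difference (limma adjusted p = 3.81e-07), by 2.52 ± 0.45 at 40 µg (limma adjusted p = 1.81e-05) and by 2.20 ± 0.45 at 20 µg (limma adjusted p = 0.000431). At 10 µg its difference of 0.97 ± 0.45 did not pass the test (limma adjusted p = 0.772). Feature 34474 fell by 1.64 at 80 µg (limma adjusted p = 0.00160), but this rested on 2 arrays of low spread, replicates 1 and 5, at 1.04 and 1.51, while the other arrays of the group lay between 5.12 and 6.04. Without the arrays of low spread its change was -0.97 and did not pass (limma adjusted p = 0.0728).

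As deposited, the day 7 counts at 80, 20 and 10 µg were not beyond what other groupings of the same arrays gave: 5, 13 and 6 of 100 splits called as many features, the real split included. Quantile normalization gave 3917 features at 80 µg, with 67.5% higher ratios in place of 51.8%. It gave 1372 at 40 µg, with 76.7% in place of 64.9%, and 465 at 20 µg, with 87.7% in place of 54.6%. Of these, 2515, 950 and 400 were also called as deposited.

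At day 28 few features were changed. At 80 µg 724 of 37864 tested features differed from vehicle, 566 with a higher and 158 with a lower ratio, and 336 by at least 1.5-fold. At 40 µg 189 features were changed (184 higher, 5 lower), at 20 µg 25, all with a higher ratio, and at 10 µg 1, with a ratio higher by 2.25. Feature 26374 was higher by 1.60 ± 0.42 (SE) at 80 µg, a 3.02-fold difference (limma adjusted p = 0.0192), and by 1.64 ± 0.42 at 40 µg (limma adjusted p = 0.0382). Feature 36981 was higher by 1.55 ± 0.45 at 80 µg (limma adjusted p = 0.0471). Neither passed when only the day 28 arrays were fitted (limma adjusted p = 0.113 and 0.191). Features 34474 and 19066 differed from vehicle by -0.52 ± 0.41 and -0.03 ± 0.74 and did not pass (limma adjusted p = 0.765 and 0.994).

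Quantile normalization gave 217 features at 80 µg, 96.3% of them with higher ratios in place of 78.2%, and 95 at 40 µg. Of these, 173 and 76 were also called as deposited. Of 100 splits of the same arrays with the deposited values, 15 called as many features as the real one at 20 µg and 29 as many at 10 µg.

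At day 56 changed features were numerous at every dose. At 80 µg 4784 of 36891 tested features differed from vehicle, 2604 with a higher and 2180 with a lower ratio, and 2244 by at least 1.5-fold. The counts were 2676 at 40 µg (1893 higher, 783 lower), 2415 at 20 µg (1184 higher, 1231 lower) and 2349 at 10 µg (1070 higher, 1279 lower), of which 615, 723 and 298 differed by at least 1.5-fold. Feature 36981 was higher by 2.10 ± 0.45 (SE) at 80 µg, a 4.27-fold difference (limma adjusted p = 0.000372), with 8 of 8 arrays above the vehicle median, and by 1.69 ± 0.45 at 40 µg (limma adjusted p = 0.00960). Its differences of 1.25 at 20 µg and 0.65 at 10 µg did not pass (limma adjusted p = 0.0821 and 0.521). Features 34474 and 19066 stood at -0.22 ± 0.41 and 0.21 ± 0.71 against vehicle at 80 µg (limma adjusted p = 0.781 and 0.881).

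Quantile normalization gave 2755 features at 80 µg and 1948 at 40 µg, the latter with 62.6% higher ratios in place of 70.7%. It gave 1330 at 20 µg, with 70.5% higher ratios in place of 49.0%, and 286 at 10 µg, with 73.4% in place of 45.6%. Of these, 2135, 1269, 950 and 264 were also called as deposited. Centring each array on its median gave 3915 features at 20 µg, 88.6% of them with higher ratios. The median change of all tested features at 20 µg was -0.08 as deposited and 0.03 after centring, so the deposited split of higher and lower ratios at that dose includes a shift. It lay in replicates 5, 6 and 8, with array medians of -0.43, -0.32 and -0.56, while the other arrays of the group had medians between -0.19 and -0.12, and the vehicle arrays between -0.18 and -0.09.

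**Figure D3:**
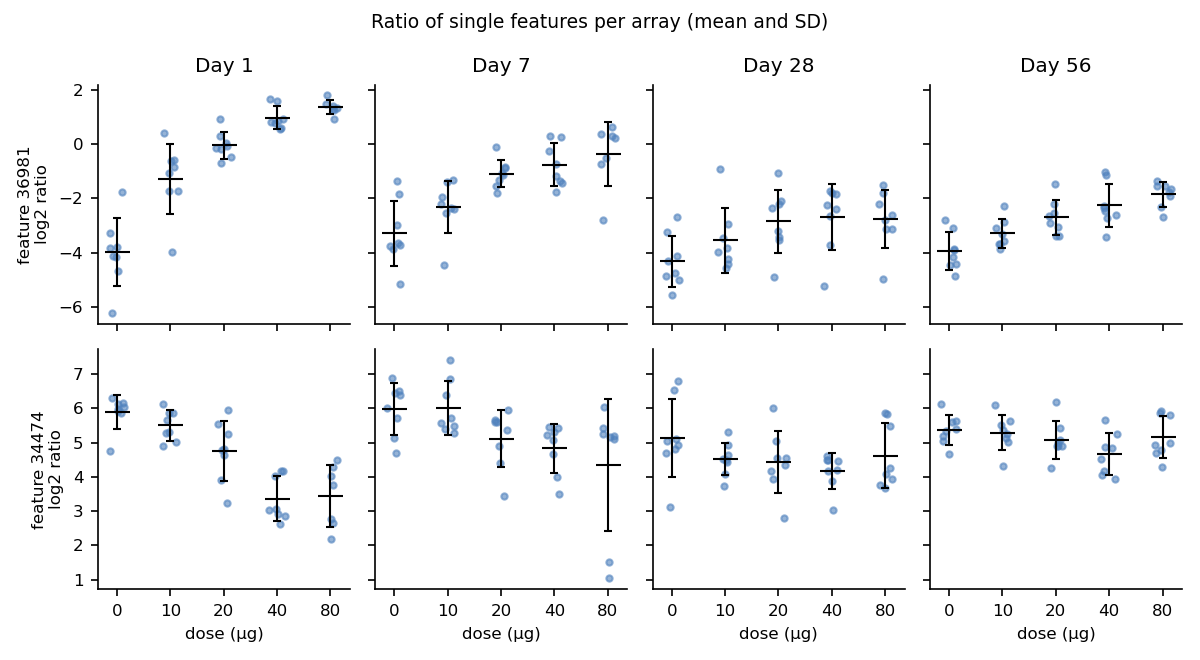
Points are single arrays, and bars give the mean and SD of each group of up to 8 arrays, for features 36981 (top) and 34474 (bottom), as log2 ratio against dose in µg at each day. Feature 36981 stood highest at 80 µg on day 1, at 1.36 ± 0.26, and the 2 low points of feature 34474 at 80 µg on day 7 are the arrays of low spread at 1.04 and 1.51.

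A linear trend over the 5 doses was found in 6951 features at day 1 (3641 rising, 3310 falling with dose), 7391 at day 7 (3887 rising, 3504 falling), 790 at day 28 (631 rising, 159 falling) and 4640 at day 56 (2519 rising, 2121 falling). As deposited, 5 of 100 splits called as many trends as the real one at day 28. After quantile normalization the trends at days 28 and 56 numbered 251 and 2838, and 3 of 100 splits called as many at day 28. To see whether features called at 80 µg moved the same way at lower doses, the vehicle arrays were divided, so that features were called against 4 of them and read against the other 4. At day 1, the 2115 features called higher against vehicle replicates 1 to 4 had median changes of 0.16, 0.24 and 0.38 at 10, 20 and 40 µg against replicates 5 to 8, and 76.7%, 84.3% and 91.7% of them lay above those vehicle arrays. The 2033 features called lower had median changes of -0.07, -0.14 and -0.24. The reverse division gave 0.13, 0.19 and 0.35 for 2296 higher features and -0.12, -0.17 and -0.30 for 1652 lower ones. At day 7 the result depended on the vehicle arrays used: among higher features the median change at 10 µg was -0.01 in one division and 0.15 in the other, and at 40 µg it was 0.16 and 0.43. At day 28 the higher features had median changes of 0.12, 0.23 and 0.41 (368 features) or 0.28, 0.47 and 0.62 (168 features). Quantile normalization gave 0.51, 0.97 and 1.26 (67 features) or 0.47, 0.90 and 1.20 (84 features). At day 56 the higher features showed little gradation, with 0.16, 0.16 and 0.18 (2257 features) or 0.22, 0.23 and 0.30 (1442 features). Quantile normalization gave 0.41, 0.49 and 0.45 (683 features) or 0.22, 0.35 and 0.35 (884 features). As deposited, the lower features at day 56 had -0.11, -0.10 and -0.06 (1813 features) in one division and 0.03, -0.11 and -0.28 (963 features) in the other. These too depended on the vehicle arrays used.

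**Figure D4:**
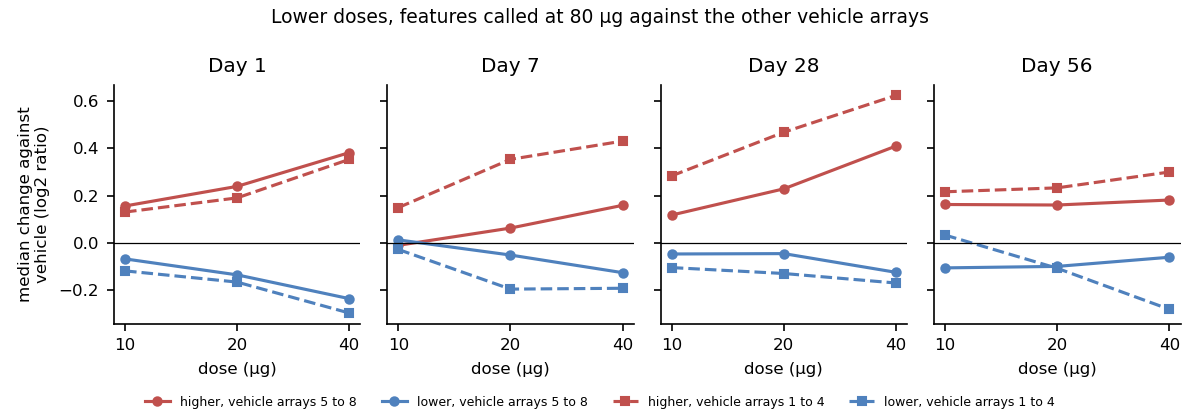
Lines give the median change in log2 ratio at 10, 20 and 40 µg for features called higher (red) or lower (blue) at 80 µg on the same day, where the call and the reading used different vehicle arrays. Medians moved away from 0 with dose at day 1, from 0.16 to 0.38 and from -0.07 to -0.24 with the solid lines. For higher features at 20 and 40 µg, the division of the vehicle arrays mattered most at day 7.

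The 80 µg changes carried over between days in part. Vehicle and treated arrays of different days were separate animals, so these overlaps share no control. They do share the estimate of each feature's spread, so features of small spread are called more easily at every day. The numbers for independent lists may therefore be too low, and by how much was not tested. Among features tested at both days, 1005 were higher at days 1 and 7 against 241.4 for independent lists, and 831 were lower at both against 203.9. Of the features higher at day 28, 500 of 557 (89.8%) were also higher at day 56, against 39.9 for independent lists. Their median change was 0.61 at day 28 and 0.71 at day 56. Of the features lower at day 28, only 56 of 154 (36.4%) were also lower at day 56, against 9.18. Changes of features higher at day 1 shrank from a median of 0.47, a value inflated by their selection, to 0.19 at day 7, 0.03 at day 28 and 0.07 at day 56, where 77.0%, 58.1% and 61.4% of them had a ratio above vehicle. Across features, which are not independent replicates, the 80 µg changes correlated at r = 0.386 between days 1 and 7 and r = 0.500 between days 28 and 56, but at r = -0.029 between days 1 and 28 and r = -0.091 between days 1 and 56. After quantile normalization these values were 0.236, 0.561, 0.043 and 0.025. Mean array spread at 80 µg lay below vehicle at days 1 and 7 and above it at days 28 and 56. The deposited correlations, and the overlaps between days 1 and 7 and between days 28 and 56, may include this gap. At all 4 days, 186 of 35810 features were higher and 17 lower, against 0.289 and 0.0567 for independent lists, and after quantile normalization 67 were higher and 3 lower. The 186 had median changes of 0.89, 0.98, 0.65 and 0.83 at days 1, 7, 28 and 56.

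The change at 80 µg was tested directly for a difference from day 1. It differed in 3203 of 38901 features at day 7, in 2793 of 37288 at day 28 and in 5212 of 36607 at day 56. At day 28, 2405 of the 2793 features had the larger change at day 1, with a median size of 0.50 at day 1 and 0.13 at day 28. At day 7 the features were divided, 1640 with the larger change at day 1 and 1563 at day 7, and at day 56 there were 3018 and 2194. Among the features whose change differed, 289 at day 7, 52 at day 28 and 317 at day 56 were called at both days in opposite directions, and 167, 52 and 172 at both days in the same direction. After quantile normalization those in opposite directions numbered 169, 10 and 121. Array spread differed between 80 µg and vehicle, and not in the same direction at every day. The mean standard deviation of the 80 µg arrays lay below vehicle by 0.154 at day 1 and 0.185 at day 7. It lay above vehicle by 0.106 at day 28 and 0.237 at day 56. How far this gap adds to the changes in opposite directions was not tested apart from quantile normalization. Features called in the same direction, whether or not the change differed, were 234 higher and 62 lower at days 1 and 28, and 641 and 230 at days 1 and 56. The change of feature 36981 minus that at day 1 was -2.42 ± 0.67 (SE) at day 7 (limma adjusted p = 0.00854), -3.79 ± 0.65 at day 28 (limma adjusted p = 5.69e-06) and -3.25 ± 0.65 at day 56 (limma adjusted p = 0.000102). That of feature 34474 was less negative than at day 1 by 1.93 ± 0.59 at day 28 (limma adjusted p = 0.0240) and by 2.23 ± 0.59 at day 56 (limma adjusted p = 0.00422). For the day 7 difference, 5 of 100 splits of the deposited values called as many features as the real one. After quantile normalization 4 of 100 did, and the differences numbered 2580 at day 7, 1180 at day 28 and 3263 at day 56.

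Without nanotubes, vehicle lungs of the 4 days differed in 21381 of 38110 features. Day 28 stood furthest from the rest: it differed from day 1 in 11288 features, from day 7 in 18537 and from day 56 in 16846. The other pairs differed in 6438 features (days 1 and 7), 6978 (days 1 and 56) and 3390 (days 7 and 56). After quantile normalization the 3 pairs with day 28 gave 7002, 16648 and 13843 features and the other pairs 4621, 3744 and 1286. Day and array batch cannot be told apart in these groups.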

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

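Of the tests in this part, those on unequal array spread, without the arrays that stand apart on component 1, on the arrays outside their day's cluster and on the size of the day 28 change against days 1 and 7 were chosen only after results were seen.

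The 80 µg change differed between days in the tests of the difference itself, in 3203 features at day 7, 2793 at day 28 and 5212 at day 56, each against day 1. For feature 36981 the change minus that at day 1 was -2.42 at day 7, -3.79 at day 28 and -3.25 at day 56. For feature 26374 these differences were -2.29, -3.70 and -3.05. For feature 34474 the difference was 1.93 at day 28 and 2.23 at day 56.

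Single arrays lay far from the rest of their group in 14 of 120 checks of array spread, number of values and the 4 followed features. Chance gives about 1 in 20 for separate checks, but these are not independent. Features 36981 and 26374 correlated at 0.987 over arrays, and some arrays were flagged more than once. The array of low spread at 20 µg, day 28, replicate 7, had a standard deviation of 0.801 against 1.56 to 1.86 in its group, 42769 features with a value, and feature 19066 at 0.71. At 20 µg, day 1, replicate 2 had a standard deviation of 1.07. Feature 34474 stood at 4.75 in vehicle replicate 3 of day 1 and at 3.02 at 40 µg, day 28, replicate 4. At 80 µg, day 7, replicate 8 had features 36981 and 26374 at -2.80 and -2.75, below the other arrays of its group. At 10 µg, day 7, replicate 7 had them at -4.44 and -4.33, and at 10 µg, day 28, replicate 1 had them at -0.92 and -1.13, above the rest. Feature 26374 was at -0.17 at 20 µg, day 7, replicate 5, and feature 36981 at -4.98 at 80 µg, day 28, replicate 3.

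At 80 µg, 724 features were called at day 28 against 6069 at day 7, a ratio of 0.119. Without the arrays that stand apart on component 1 the ratio was 0.131 (718 against 5464), which argues against these 10 arrays alone as the cause of the low count. Unequal spread stays open, since the ratio was 0.0386 with all arrays at a common spread (264 against 6831) but 0.255 without arrays of low spread (1065 against 4170), and so does uneven precision of single arrays, since array quality weights gave 3840 against 6071, although the median replicate standard deviation at day 28 was 0.242 against 0.227, 0.301 and 0.232 at days 1, 7 and 56. A smaller effect at day 28 stays open as the biological explanation: for features called alike at days 1 and 56, the median change at day 28 was 0.585 times that at day 7 (jackknife standard error over arrays 0.162), and 0.655 times (0.180) after quantile normalization, where the interval reached 1.01. Over features called alike at days 7 and 56, it was 1.35 times that at day 1 (0.343, and 1.74 with 0.523 after quantile normalization). With calls at days 1 and 7, it was 1.03 times that at day 56 (0.274, and 0.788 with 0.159). Both are too wide to tell an equal from a smaller change. Changes at day 56 correlated with those at day 28 (r = 0.500) but not day 1 (r = -0.091), so the ratio of 1.35 favours day 28. For the ratio of 0.585, calls at day 1 favour day 7. Changes at day 1 correlated with those at day 7 (r = 0.386) but not day 28 (r = -0.029). The calls at day 56 that it also used favour day 28 (r = 0.500, against 0.159 with day 7). In the direct test, 2405 of 2793 differing features had the larger change at day 1 (1040 of 1180 after quantile normalization). These features were selected for differing, and 2263 of the 2793 were called at day 1 only. For them the change was smaller at day 28, but this largely repeats the low count and does not tell its cause.

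At day 56, 10 µg gave 2349 features, close to 20 and 40 µg. Quantile normalization gave 286 (12.2% as many), of which 264 were among the 2349. Over the 2349 features the median change after it was 0.945 times the deposited one (jackknife standard error over arrays 0.0821), from 0.35 to 0.33, while the median standard error rose from 0.09 to 0.14, so most calls ended through lower precision and not through smaller changes. Unequal spread between the groups would shrink the changes under this normalization and drive most calls the same way relative to 0, but 51.8% moved away from 0, which argues against it as the source of the changes, while a first test, the Spearman correlation of the change with the vehicle level, was inconclusive (0.10 over all tested features, 0.042 among the calls). A low-dose response in the direction of the 80 µg response is the biological explanation, and it stays open. With separate vehicle arrays for each dose, the 10 and 80 µg changes correlated at 0.312 across features. This lay above the median of 99 permuted splits of the vehicle and 10 µg arrays (-0.064) but below their highest (0.53). An offset of the vehicle arrays, which all doses of day 56 share, also stays open and was not tested. The little gradation over dose among higher features does not separate it from a low-dose response. Vehicle replicate 1 had an array quality weight of 0.083, yet with these weights the 10 µg count was 8702.

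Vehicle lungs of the 4 days differed in 21381 features, and of the separate tests of pairs of days, those with day 28 gave the most calls (11288, 18537 and 16846). In correlation with the other arrays, 4 day 28 arrays were closest to those of another day, all of them replicate 1 (vehicle, 10, 20 and 40 µg), so an array batch that follows day 28 with replicate 1 mostly outside it is a candidate explanation. Being closest to another day was not particular to day 28, as 20 day 7 arrays, 3 day 1 arrays and 4 day 56 arrays were too. Only 1 array of another day, day 7 vehicle replicate 1, was closest to day 28, so a swap of day 28 labels with another day has 1 partner out of place for the 4, which neither shows nor excludes it. Time after aspiration and the age of the mice stay open, as untested.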

How the results depend on the processing

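The number of changed features depended strongly on how the arrays were treated, while no followed feature that passed the test at 80 µg changed direction under the alternatives run for it. The followed features were not rerun at lower doses, and only feature 26374 had a value on every array. Counts stayed within 1.5 times for all 24 comparisons with a robust variance estimate and for all 4 trends with the rank of the dose. The cause was not tested except where noted. Gene lists and one probe per gene were not run, since features were not paired with genes. The median of all features at 20 µg, day 56, moved from -0.08 to 0.03 with centred arrays and with a common spread, and no scaling moved the median of another comparison by over 0.1. Signal over background is unknown for these ratios, so what it limits is not known.

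Centring arrays on their median moved 1 count, 20 µg at day 56, to 3915. Quantile normalization lowered 17 counts: at day 1 to 184, 657, 2435 and 3602 at 10, 20, 40 and 80 µg, at day 7 to 465, 1372 and 3917 at 20, 40 and 80 µg, at day 28 to 5, 95 and 217 at 20, 40 and 80 µg, and at day 56 to 286, 1330 and 2755 at 10, 20 and 80 µg. It also lowered the trends to 251 at day 28 and 2838 at day 56, and the differences from day 1 to 1180 at day 28 and 3263 at day 56.

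Scaling also moved the share of higher ratios among the calls. At 10 and 20 µg, day 1, the shares of 70.6% and 65.2% became 82.3% and 78.6% with centred arrays and 82.3% and 78.0% with a common spread. At 20 µg, day 7, 54.6% became 67.2% and 80.2%, and at 40 µg, day 7, 64.9% became 78.4% with a common spread. At 80 µg, day 28, 78.2% became 90.9% and 93.9%, and for the day 28 trend 79.9% became 93.1% and 95.3%, with 97.2% after quantile normalization. At 10 and 20 µg, day 56, 45.6% and 49.0% became 55.9% and 88.6% with centred arrays and 61.6% and 86.5% with a common spread. For the trends at days 1, 7 and 56, the rising shares of 52.4%, 52.6% and 54.3% became 47.9%, 47.4% and 48.1% with centred arrays. Falling trends were then the majority. After quantile normalization the rising shares were 48.9%, 60.8% and 45.1%.

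Fitting only the arrays of the day or groups compared moved 10 counts: 10 µg at day 1 to 1420, 10, 20, 40 and 80 µg at day 7 to 6, 437, 1034 and 3434, 10, 20 and 40 µg at day 28 to 0, 0 and 45, the day 7 trend to 4231 and the day 7 difference from day 1 to 1431. Both counts of 0 were from limma, with 555 and 911 features at an unadjusted p under 0.05 at 10 and 20 µg.

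The replicate numbers were not taken to pair the arrays, since no label says so and not every pair of the same number correlated above 0.1. Deviations of arrays with the same number correlated between -0.65 and 0.75 at day 1, -0.45 and 0.82 at day 7, -0.54 and 0.82 at day 28 and -0.62 and 0.79 at day 56, with means of 0.037, 0.282, 0.174 and 0.072, against 0.004, -0.033, 0.008 and -0.006 for different numbers. Of 40 arrays a day, 8, 18, 14 and 12 correlated best with their own number, where chance gives 5. This is a hint from the data that some arrays of one number share a structure, most at days 7 and 28. Failing the rule above does not show that such a structure is absent. The main fit and the splits did not take it into account. How far the numbers of splits at day 7 depend on it was not tested. With a replicate block within each day 13 counts were higher: 1683 and 3641 at 10 and 20 µg, day 1, 197, 3279 and 3716 at 10, 20 and 40 µg, day 7, 42, 297 and 1327 at 20, 40 and 80 µg, day 28, 4252, 4571 and 4808 at 10, 20 and 40 µg, day 56, 1567 for the day 28 trend and 5008 for the day 7 difference from day 1.

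Array quality weights moved 19 counts: at 10, 20, 40 and 80 µg to 4150, 7545, 12404 and 10168 at day 1, 807, 605, 3110 and 3840 at day 28 and 8702, 6313, 10294 and 14757 at day 56, at 10 and 20 µg to 381 and 662 at day 7, the trends to 3428 at day 28 and 14630 at day 56, and the differences from day 1 to 5474, 6619 and 13279 at days 7, 28 and 56. The weights were estimated from the same arrays, and their p-values take them as known.

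Restriction to the upper 50% of features by interquartile range tested fewer features and lowered 20 counts: to 287, 681, 1064 and 1468 at day 1, 607, 720 and 1491 at day 7 (20, 40 and 80 µg), 374 at day 28 (80 µg), 171, 489, 667 and 2407 at day 56, the trends to 1951, 1913, 385 and 2640 at days 1, 7, 28 and 56, the differences from day 1 to 793, 659 and 1903 and vehicle lungs among days to 10774.

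The next alternatives were chosen after seeing the data. Arrays scaled to a common spread gave 395 and 1423 at 10 and 20 µg, day 1, 771 and 1473 at 20 and 40 µg, day 7, 0, 4, 80 and 264 at 10, 20, 40 and 80 µg, day 28, 705 and 3142 at 10 and 80 µg, day 56, and 321 for the day 28 trend. Without arrays of low spread the counts were 1371 at 10 µg, day 1, 4255 at 40 µg, day 7, 2 at 10 µg, day 28, and 4568 for the day 7 trend. Without arrays that stand apart on component 1 they were 84 and 1077 at 10 and 20 µg, day 7, and 2 and 3 at 10 and 20 µg, day 28. Features measured on every array, which are fewer, gave 0 and 11 at 10 and 20 µg, day 28, 2971 at 80 µg, day 56, 2809 for the day 56 trend and 12780 for vehicle lungs among days. The counts of 0 at 10 µg, day 28, were from limma, with 375 features at an unadjusted p under 0.05 after scaling and 305 among features measured on every array.

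Of the followed features at 80 µg, features 36981 and 26374 at day 28 lost the call with only the arrays of that day (changes of 1.55 and 1.60). Feature 34474 lost the call at day 7 with array quality weights (-0.61), a common spread (-0.76) and without arrays of low spread (-0.97), and gained one at day 28 with array quality weights (-1.09).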

Other observations

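Of the tests in this part, those on the sign of the deposited ratio, without arrays of low spread and without arrays that stand apart were chosen only after the file was seen. At 80 µg, 422 features were higher and 123 lower at days 1, 7 and 56, against 18.6 and 13.2 for independent lists. After quantile normalization these numbered 203 and 38, against 5.69 and 2.02. The numbers for independent lists may be too low, since all days share one estimate of each feature's spread. The 422 and 123 include the 186 and 17 that were also called that way at day 28. Of the 236 higher features not called higher at day 28, 93.2% had a ratio above vehicle then, and of the 106 lower features not called lower, 95.3% had a ratio below it.

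Other splits of the same arrays showed which counts chance can account for. Each was set against 100 splits, the real one included. At day 1, 2, 1, 1 and 1 splits called as many features as the real ones (805, 2358, 4058 and 5708 at 10, 20, 40 and 80 µg). The highest other splits called 1148, 335, 390 and 4034, so chance can be excluded at 20, 40 and 80 µg. At 10 µg another split called more than the real one, so chance is unlikely but not excluded. At day 7, 6, 13, 1 and 5 splits called as many (131, 1686, 2296 and 6069 features), with 1203, 8899, 573 and 9040 in the highest others. For the deposited counts, chance can therefore be excluded at 40 µg only. After quantile normalization 2 of 100 splits called as many at 40 µg (1372 features, highest other 2563), so chance is then unlikely but not excluded. Of the 80 µg calls, 1005 higher and 831 lower features were called alike at day 1, and 136 and 153 in the opposite direction. At day 28, 436 and 120 were called alike and 0 in the opposite direction. These overlaps argue against chance for the features they cover, not for the count. At day 28, 29, 15, 4 and 1 splits called as many (1, 25, 189 and 724 features), with 3037, 2697, 2382 and 339 in the highest others. Chance can be excluded at 80 µg only. At 40 µg, 4 of 100 splits called as many and another called 2382 features, so chance is not clearly excluded. At day 56, 1, 1, 1 and 1 splits called as many (2349, 2415, 2676 and 4784 features), with 294, 1819, 601 and 1181 in the highest others. Chance can therefore be excluded at every dose with the deposited values. After quantile normalization 2 of 100 splits called as many at 20 µg (1330 features, highest other 1628), so chance is unlikely but not excluded there.

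For the trends, 2, 1, 5 and 1 splits called as many at days 1, 7, 28 and 56 (6951, 7391, 790 and 4640 features), with 11332, 6762, 4403 and 227 in the highest others. Chance cannot be excluded at day 28 with the deposited values, and at day 1 another split called more than the real one. After quantile normalization 3 splits called as many at day 28 (251 features, highest other 9687), which does not clearly exclude chance. At days 1 and 7 another split then called more than the real one (15776 against 5432 and 10822 against 5045 features). Chance is therefore unlikely but not excluded at either. For the differences from day 1, 5, 1 and 1 splits called as many at days 7, 28 and 56 (3203, 2793 and 5212 features), with 10035, 236 and 1321 in the highest others, so chance cannot be excluded at day 7 with the deposited values. After quantile normalization 4 splits called as many at day 7 (2580 features, highest other 12977), which does not clearly exclude chance either. The verdicts on the day 28 trend and the day 7 difference lie near the threshold and depend on the normalization. For vehicle lungs among days 1 split called as many (21381 features), with 8275 in the highest other, so chance can be excluded.

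Splits that call several times the real count point to a structure of the arrays within groups. At 80 µg, day 7, the splits that called as many as the real one set the mean standard deviation of the arrays on their sides 0.419 apart, against 0.160 in the other splits and 0.185 in the real one. At 20 µg, day 7, the number of calls over the splits rose with the gap between sides on component 1 (Spearman correlation 0.475 over 99 splits). Quantile normalization, which removes differences in spread, did not end this: 11 of 100 splits then called as many as the real one at 80 µg, day 7 (3917 features, highest other 10412), and 14 at 20 µg, day 7 (465 features, highest other 10474). Without the arrays of low spread the 80 µg, day 7 count was 4170, and without those that stand apart on component 1 it was 5464.

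The sign of the deposited ratio was tested through missing values. If lung RNA is the numerator, features whose ratio rises with dose have brighter lung signal and may be missing less often at high dose. Over the 300 features per day with the clearest dose slope, the slope of the ratio and the slope of missingness correlated at -0.478, -0.170, -0.200 and -0.197 at days 1, 7, 28 and 56. Their sum of -1.05 lay below all 99 sums with doses permuted within days, the lowest of which was -0.801. Taken singly, 0, 8, 26 and 4 of 99 permutations lay at or below the value at days 1, 7, 28 and 56. At day 1, arrays of low spread, which have few missing values, numbered 1 in vehicle and 2 each at 40 and 80 µg. Dose and array quality are therefore not separated there. That lung is the numerator, so that a higher ratio would mean higher expression in lung, is a hypothesis. It rests mainly on day 1 and on how the missing values arose.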
